A study of Homo sapiens with 18 samples.

How the data were processed

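The study measured polyadenylated RNA in D425 and D458, 2 established cell lines of Group 3 medulloblastoma, a childhood tumour of the cerebellum, after short hairpin RNAs against EYA2 or a non-targeting control hairpin had been introduced. Per the labels, each line had a control group and 2 hairpin groups of 3 biological replicates each, 18 libraries in 6 groups. D425 received hairpins 6 and 8, and D458 received hairpins 7 and 8. Cells were selected in puromycin at 1 µg/mL for 48 h, the top 10% by zsGreen fluorescence were sorted, and RNA was taken after 24 h of recovery, per the labels' protocols. Libraries were stranded, per the same protocols.

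The deposited table held whole-number read counts for 25369 gene symbols, 1 column per library, with no normalization. Reads were processed with bcl2fastq, FastQC, TopHat2, Bowtie2, SAMtools, Picard and HTSeq on the human builds GRCh37 and hg19, per the submitters' processing notes. Tool versions, the order of the steps, the strand setting of the counting and the handling of reads that map to several places are not given in the sources used here. For that reason, overlapping antisense pairs (DPP10 and DPP10-AS1) and near-identical gene copies (zinc finger, globin and histone families) are reported as uncertain. Genes are named by the symbols in the table, which include older ones (LPHN3, CIRH1A, HIST1H2BG).

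From these counts, all values in the report were computed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept with filterByExpr on the group design (minimum count 10), which left 14850 genes and removed 10519. Library totals ran from 21260369 to 31552051 counts. Libraries were scaled by TMM factors, and levels are given as TMM-scaled CPM, from the cpm function of edgeR, with the SD over 3 libraries. One edgeR quasi-likelihood model with robust estimation was fitted to all 18 libraries with 1 coefficient per group (12 residual degrees of freedom, common biological coefficient of variation 0.153). Log2 fold changes carry the standard error given by the quasi-likelihood F statistic. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and each adjusted p in the text comes from this test unless another tool is named. Against a group with no counts, a fold is given as a lower bound with 3 counts per library as the floor, and for groups with 1 to 3 counts the counts are given. Such floors and the error of a count cover counting error only.

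There were 8 comparisons: each of the 4 hairpin groups against its line's control, the hairpins of a line against each other, the hairpin 8 effect in D458 minus that in D425, and the control groups of the lines. Genes called in the same direction with both hairpins of a line were counted. Because both comparisons use the same 3 controls, unchanged groups were simulated beside shared simulated controls, and the overlap of independent lists was computed. All libraries of the line, controls included, were redrawn as independent counts at its control rate. Deviations of the real control libraries were thus left out. The controls could not be split into parts of at least 2 libraries.

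Lists of genes for 37 pathways and cell types were written from general knowledge. In each comparison the called members were counted, over all genes tested and adjusted over the list alone, and the lists were tested with camera of limma at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each with Benjamini-Hochberg adjustment over the lists. The comparisons, tests, lists and alternatives, and the rule for naming genes, were fixed before the data were examined, except where the text says otherwise. The rule names EYA2 and tested genes of its network with MYC, MYCN and OTX2. It also names, per line, the 10 higher and 10 lower genes with the largest smaller change over both hairpins among genes called with both and averaging at least 1 CPM. The 5 higher and 5 lower genes with the largest change in each hairpin comparison and in the difference between lines are included, with 10 each for the control groups, at the same level. From each list described, up to 4 called members with the smallest adjusted p are named. Symbols of uncharacterized loci, small RNAs and genes that mark donor sex were passed over (9 cases). Some genes that the rule names are not reported here. Genes named outside the rule are marked where they appear.

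Per the labels, libraries with the same replicate number shared a run label in every group. Replicates 2 and 3 of every group carried the same date in the labels, and replicate 1 an earlier one. After removal of group means, libraries of a line that shared a number correlated at 0.08 to 0.61 in D425 (mean 0.30) and 0.13 to 0.70 in D458 (mean 0.35), and libraries with different numbers at means of -0.14 and -0.17. Among the latter, pairs of replicate 1 with 2 or 3 all correlated negatively (means -0.28 and -0.32) and pairs of replicates 2 and 3 positively (means 0.14 and 0.15), so replicate 1 stood apart. Deviations in a group cancel out once its mean is removed. The negative means for different numbers therefore follow largely from the positive means for shared numbers and are not separate evidence of pairing. The numbers were taken as pairs from the labels. The fit fixed before the data were examined had no block, and the fit with the replicate number as a block (8 residual degrees of freedom) is an alternative, given beside a result where it changed a call or moved a count by more than 1.5 times. The other alternatives were RLE size factors, no filter on low counts, DESeq2, only the 9 libraries of a line, and leaving out each library and each replicate number in turn. Of 732 named changes that were called, 500 stayed called whichever single library of the compared groups was left out, and 280 stayed called whichever replicate number was left out. List members named in the report are from those 500 unless the text says otherwise.

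The fit was tested on simulated counts for the real genes with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. For D425 hairpin 6 against control, 47.8% of genes changed 1.5-fold, 76.1% changed 2-fold and 92.4% changed 4-fold were recovered among 14520 genes, and 3.36% of calls were false. For the difference between lines these shares were 23.9%, 46.3% and 83.3% among 14322 genes, with 1.92% false. Over the 8 comparisons the share of false calls ran from 1.92% to 8.0%. A list planted with a 1.3-fold change was found, and 1 of the other lists was called with it. Simulated counts were drawn independently for each gene and library, with the spread of each gene estimated from these data. These tests therefore do not cover genes that vary together or libraries that share a run or date.

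Chromosomes and gene order were taken from RefSeq annotation of GRCh38.p14, in which 14505 of the 14850 tested symbols (97.7%) had a chromosome. GC content and transcript length were those of the longest GENCODE transcript of each gene symbol. No coordinates are given, since the counts were made on another build. Shifts of whole chromosomes were tested against 1000 random draws of genes. Sequence-level data were not used here.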

Results

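RNA of D425 and D458 cells was sequenced after EYA2 had been targeted with short hairpin RNAs, 2 hairpins per line beside a non-targeting control hairpin. EYA2 encodes a transcriptional coactivator and tyrosine phosphatase that works with homeobox proteins, and both lines are models of Group 3 medulloblastoma. D425 received hairpins 6 and 8, and D458 received hairpins 7 and 8, with 3 biological replicates in each of the 6 groups. The 18 libraries held 21260369 to 31552051 counts each, and 14850 genes were tested. Adjusted p values are from edgeR quasi-likelihood tests with Benjamini-Hochberg correction unless another tool is named, and errors of log2 changes are standard errors.

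The level of EYA2 was read first, to see how far the target fell with each hairpin. In D425, EYA2 fell from 27.9 ± 14.3 CPM (mean and SD, n = 3) to 11.9 ± 2.87 with hairpin 6 and 14.1 ± 3.01 with hairpin 8, log2 changes of -1.24 ± 0.27 (adjusted p = 0.0069) and -0.98 ± 0.27 (adjusted p = 0.017). In D458 it fell from 70.3 ± 3.16 to 20.3 ± 2.77 CPM with hairpin 8, a log2 change of -1.79 ± 0.27 (adjusted p = 5.1e-04). With hairpin 7 the mean was 48.1 ± 3.43 CPM, and the change of -0.55 ± 0.26 did not pass (adjusted p = 0.137, 95% interval -1.12 to 0.02). The remaining EYA2 RNA was thus 42.4% and 50.5% of control in D425, and 68.4% and 28.9% in D458. In D425 the genes of chromosome 20, which carries EYA2, were lower as a whole (medians -0.28 and -0.31, genes averaging at least 8 CPM). Part of the D425 fall may thus belong to that shift. The D425 controls ran from 15.5 to 43.6 CPM, yet EYA2 was below its same-numbered control in all 12 hairpin libraries. With the replicate number as a block, hairpin 7 gave -0.55 ± 0.14 and passed (adjusted p = 0.00692), as it did in the fit of the 9 D458 libraries alone (adjusted p = 0.00819). In the 9 D425 libraries alone, the D425 hairpin 8 change did not pass (adjusted p = 0.0759). The D425 hairpin 8 change did not pass without control replicate 1 (-0.51, adjusted p = 0.0865), hairpin 8 replicate 2 (-0.89, adjusted p = 0.0571), hairpin 8 replicate 3 (-0.92, adjusted p = 0.0601) or replicate number 2 (-0.97, adjusted p = 0.168). The D425 hairpin 6 change did not pass without replicate number 2 (-1.26, adjusted p = 0.154) or 3 (-1.40, adjusted p = 0.0542). It was weakest, at -0.76, without control replicate 1.

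**Figure D1:**
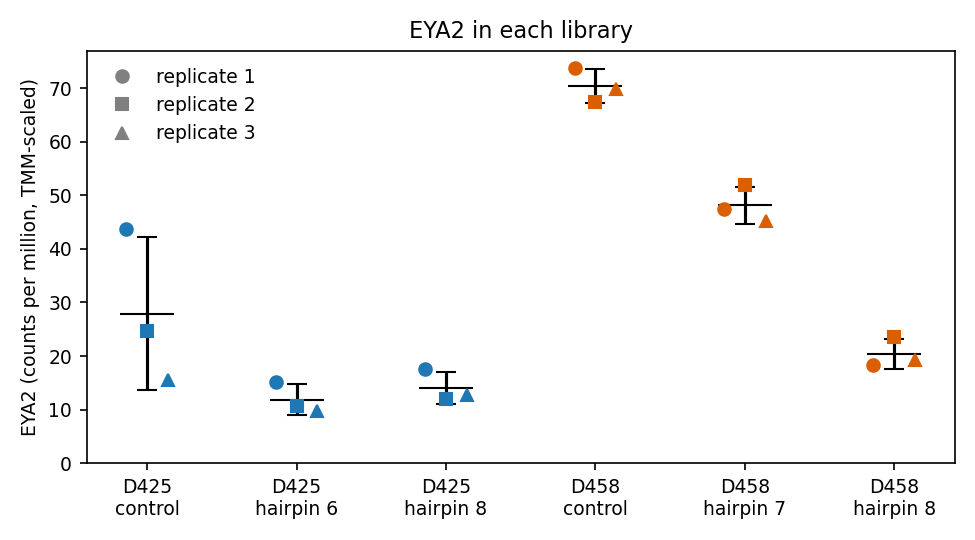
EYA2 in CPM (TMM-scaled) in each library of the 6 groups; points are replicates, bars are group means and error bars are SD (n = 3). EYA2 was lower in the hairpin groups of both lines, and hairpin 7 left the largest share of the control level.

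The partners and paralogs of EYA2 were read next, to ask whether its family moved with it. SIX2, a homeobox factor of the same network, fell in D425 from 87.7 CPM to 53.1 with hairpin 6 and 48.9 with hairpin 8, log2 changes of -0.72 ± 0.11 (adjusted p = 7.2e-04) and -0.84 ± 0.11 (adjusted p = 1.5e-04, n = 3 per group). In D458 SIX2 did not pass (0.12 ± 0.12 and -0.04 ± 0.12). DACH1, a corepressor of the network, fell in D425, with changes of -1.08 ± 0.32 (adjusted p = 0.033) and -1.07 ± 0.32 (adjusted p = 0.025). SIX4 fell with D425 hairpin 6 (-0.44 ± 0.14, adjusted p = 0.046) and did not pass with hairpin 8. In D458, SIX3 rose by 0.37 ± 0.11 (adjusted p = 0.024) and 0.35 ± 0.11 (adjusted p = 0.031), and SIX5 rose with hairpin 7 (0.28 ± 0.10, adjusted p = 0.046). SIX2 kept its calls when any single library was left out. DACH1 lost them without D425 control 2 or control 3, among others (highest adjusted p = 0.151 and 0.115), SIX4 without each of the 6 libraries (highest 0.185), SIX3 without D458 control 1 or 3, replicate 1 or replicate 2 of the hairpin (highest 0.0882 and 0.117) and SIX5 without 5 of 6 (highest 0.177). EYA1 (0.53 ± 0.19, adjusted p = 0.058) and EYA3 (-0.29 ± 0.11, adjusted p = 0.078) did not pass with D458 hairpin 7, nor did they with hairpin 8. SIX5 did not pass with D458 hairpin 8 (0.24, adjusted p = 0.08). With the replicate block within line it did, the SIX5 log2 fold change, D458 hairpin 8 against control, having an adjusted p of 0.0423. With the replicate block, EYA1 and EYA3 passed with both D458 hairpins (EYA3 adjusted p = 0.0156 and 0.0176). The EYA1 log2 fold change, D458 hairpin 7 against control, then had an adjusted p of 0.00139, and hairpin 8 gave 0.0107.

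MYC and OTX2, 2 drivers of Group 3 tumours, were looked at for the same reason. MYC fell in D425 from 3581 CPM to 2663 and 2447, log2 changes of -0.43 ± 0.10 (adjusted p = 0.0073) and -0.55 ± 0.10 (adjusted p = 9.4e-04), and kept these calls without any single library. In D458 the MYC changes of -0.24 ± 0.10 (adjusted p = 0.076) and -0.25 ± 0.10 (adjusted p = 0.065) did not pass, and with the block they did (adjusted p = 0.0084 and 0.0060). Without D458 hairpin 8 replicate 3 the D458 hairpin 8 change of MYC also passed. OTX2 did not pass with any hairpin, the largest change being -0.24 with D425 hairpin 8 (adjusted p = 0.16), and with the block it passed with both D425 hairpins (adjusted p = 0.040 and 0.0034). MYCN was near the limit of detection in D425, at 7 counts in the 3 controls, 31 with hairpin 6 and 46 with hairpin 8. Its D425 hairpin 8 change of 2.61 ± 0.77 passed (adjusted p = 0.024) but not without control 2, control 3 or hairpin 8 replicate 1 (highest adjusted p = 0.120).

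Each D425 hairpin was compared with control to find the genes that follow it. Hairpin 6 changed 2101 genes (1086 higher, 1015 lower; 550 higher and 190 lower at least 2-fold) and hairpin 8 changed 3221 (1716 higher, 1505 lower; 826 higher and 241 lower at least 2-fold), with n = 3 per group. DESeq2 called 2541 and 3671, and the replicate block 4134 and 5521. The hairpin 6 count was 1196 without control replicate 2, 926 without control replicate 3, 1272 without hairpin 6 replicate 1, 1266 without hairpin 6 replicate 3, and 3439, 116 and 135 without replicate number 1, 2 and 3. The hairpin 8 count was 2108 without control replicate 2, 1584 without control replicate 3, 2018 without hairpin 8 replicate 1, and 878 and 513 without replicate number 2 and 3.

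Genes changed in the same direction by both D425 hairpins were counted, since 2 hairpins rarely share other targets. There were 963 higher and 882 lower, against 125 and 103 for independent lists, and none was called in opposite directions. GLI3, a transcription factor of hedgehog signalling, rose from 0.402 CPM to 8.60 and 8.99, by 4.39 ± 0.40 (adjusted p = 1.1e-05) and 4.45 ± 0.40 (adjusted p = 7.2e-06). STK32B, a serine/threonine kinase, rose 36.5-fold and 35.3-fold (5.19 ± 0.51 and 5.14 ± 0.51, adjusted p = 2.5e-05 and 1.5e-05), and the keratin KRT17 rose 24.5-fold and 25.6-fold (adjusted p = 6.4e-05 and 4.0e-05). The cell cycle inhibitor CDKN2B rose by 3.76 ± 0.78 and 4.13 ± 0.78 (adjusted p = 0.0048 and 0.0019), and the interleukin 6 receptor gene IL6R by 3.83 ± 0.74 and 3.78 ± 0.74 (adjusted p = 0.0028 and 0.0022). SLCO4A1 (3.68 and 3.44), OR51B5 (3.67 and 3.43), SIAH2 (3.27 and 3.38) and TRIML2 (4.18 and 3.34) also rose.

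Among the genes lower with both D425 hairpins, C1QL1, a secreted synaptic protein, fell from 85.3 CPM to 4.41 and 3.35, log2 changes of -4.27 ± 0.30 (adjusted p = 1.1e-06) and -4.67 ± 0.30 (adjusted p = 6.3e-07). The lactate exporter SLC16A3 fell from 133 CPM to 18.3 and 18.4, log2 changes of -2.86 ± 0.50 (adjusted p = 0.0019) and -2.85 ± 0.50 (adjusted p = 0.0012). The receptor genes KISS1R (-3.68 ± 0.59 and -4.37 ± 0.61) and TNFRSF8 (-3.14 ± 0.53 and -3.31 ± 0.53) fell as well, as did NDUFA4L2 (-3.31 ± 0.43 and -2.70 ± 0.40) and C3orf70 (-3.02 ± 0.59 and -3.44 ± 0.61). KLKB1 had 338 counts in the controls and 2 and 1 with the hairpins. ZNF98, ZNF732 and ZNF876P were also lower, with the uncertainty of near-identical gene copies.

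Over all genes, the 2 D425 hairpin effects correlated at r = 0.907 (rho 0.868), with 84.4% of genes on the same side of 0; genes are not independent replicates. Unchanged groups with shared controls, all simulated at the control rate, gave r = 0.490, 66.0% and a covariance of 0.0617. The observed covariance was 0.503, a difference of 0.442, and no gene was called by both in any of 20 simulations. The simulated controls did not carry the deviations of the real control libraries. The 3 controls could not be divided between the hairpins, so part of the excess may come from the shared controls. With the block, 3564 genes were shared. The shared count was 1066 without control replicate 2, 807 without control replicate 3, 1161 without hairpin 6 replicate 1, 1187 without hairpin 6 replicate 3, and 2884, 111 and 127 without replicate number 1, 2 and 3.

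The same questions were asked in D458. Hairpin 7 changed 3357 genes (1715 higher, 1642 lower; 809 higher and 154 lower at least 2-fold) and hairpin 8 changed 3442 (1792 higher, 1650 lower; 817 higher and 135 lower at least 2-fold), with n = 3 per group, although EYA2 itself passed only with hairpin 8. DESeq2 called 3876 and 3939, and the replicate block 5937 and 5888. The hairpin 7 count was 2077 without control replicate 2, 1916 without control replicate 3, 1283 without hairpin 7 replicate 1, and 686 and 663 without replicate number 2 and 3. The hairpin 8 count was 2244, 2179 and 1976 without control replicate 1, 2 and 3, 1458 without hairpin 8 replicate 1, and 2235, 818 and 918 without replicate number 1, 2 and 3.

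Both D458 hairpins raised 1378 genes and lowered 1283, against 207 and 182 for independent lists, and none was called in opposite directions. COL4A5, a basement membrane collagen, rose from 1.37 CPM to 28.5 and 31.6, by 4.38 ± 0.40 (adjusted p = 7.7e-06) and 4.53 ± 0.40 (adjusted p = 5.8e-06). The phosphatase gene PTPN3 rose 31.4-fold and 35.3-fold (4.97 ± 0.71 and 5.14 ± 0.71, adjusted p = 3.0e-04 and 2.3e-04). CRISPLD1 (4.89 ± 0.85 and 5.14 ± 0.84), the transcription factors CREB3L1 (4.38 ± 0.67 and 4.58 ± 0.66) and ZNF536 (3.88 ± 0.52 and 3.94 ± 0.52) rose too. CILP, a matrix protein, fell to 0.255 and 0.455 CPM, 159-fold and 91.3-fold (adjusted p = 2.7e-07 and 2.1e-07). SLC16A3 fell here as in D425, from 15.1 CPM to 0.387 and 0.386 (-5.28 ± 0.77 and -5.28 ± 0.76, adjusted p = 4.8e-04 and 4.4e-04). WNK2, a kinase that restrains growth signalling, fell from 83.9 CPM to 11.2 and 11.1 (-2.91 ± 0.18 and -2.92 ± 0.18, adjusted p = 2.7e-07 and 2.1e-07).

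Further genes lower with both D458 hairpins were ADAMTS2 (-3.83 ± 0.40 and -4.47 ± 0.42), COL21A1 (-3.36 ± 0.57 and -3.71 ± 0.58), LPHN3 (-3.65 ± 0.39 and -3.23 ± 0.38) and NTSR1 (-3.42 ± 0.51 and -3.21 ± 0.50). SLC5A1, a glucose transporter, had 465 counts in the controls and 0 with either hairpin, at least 52.2-fold and 56.6-fold lower, and DESeq2 did not call it (adjusted p = 0.149 and 0.144). DPP10 and DPP10-AS1 were lower as well, with the uncertainty of an antisense pair. The photoreceptor arrestin gene SAG, higher with both hairpins, lost its call without hairpin 7 replicate 1, D458 control 2 or control 3 (highest adjusted p = 0.104) and without hairpin 8 replicate 1 (adjusted p = 0.0685).

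Over all genes, the D458 hairpin effects correlated at r = 0.895 (rho 0.894), with 88.8% of genes on the same side of 0, and genes are not independent replicates. The simulation with unchanged groups gave r = 0.508, 65.9% and a covariance of 0.0795 against 0.588 observed, a difference of 0.508, and no shared gene in 20 simulations. As in D425, part of the excess may come from the shared controls. With the block, 4867 genes were shared. The shared count was 1720, 1614 and 1471 without control replicate 1, 2 and 3, 1188 without hairpin 7 replicate 1, 1331 without hairpin 8 replicate 1, and 531 and 556 without replicate number 2 and 3.

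**Figure D2:**
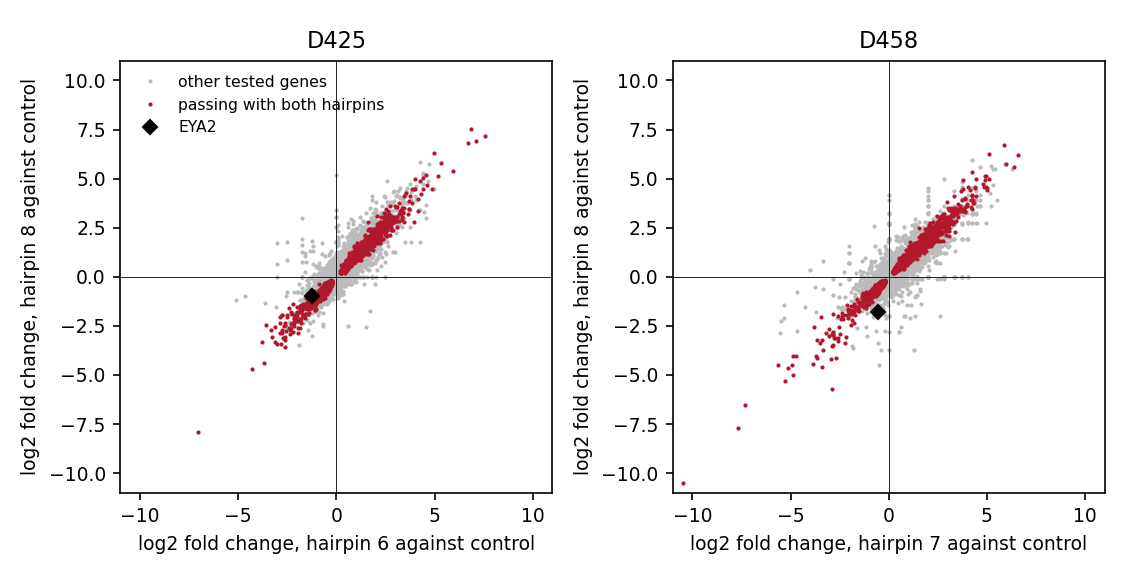
Log2 fold change of each gene against control with the first hairpin (6 or 7, horizontal) and hairpin 8 (vertical) in each line; red points are genes that passed with both and the black diamond is EYA2. In D458 most genes changed alike with hairpins 7 and 8 while EYA2 lay off the diagonal.

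Hairpin 8 was used in both lines, which allows its effects to be laid side by side. It raised 378 genes and lowered 302 in both lines, against 207 and 167 for independent lists, and 193 genes were called in opposite directions. The effects correlated at r = 0.27 across genes, which are not independent replicates. All 4 comparisons shared 172 higher and 118 lower genes, against 89.4 and 76.2 for independent lists of the genes shared within each line, and the lines have no library in common. Opposite directions in the lines held 35 and 64 genes, against 83.2 and 81.8. From these, chosen after their values were seen, COL4A5 (3.99, 4.45, 4.38 and 4.53 in the order D425 hairpin 6, D425 hairpin 8, D458 hairpin 7, D458 hairpin 8) and PDE6B (2.43, 2.66, 2.31 and 2.28) rose. SLC16A3 (-2.86, -2.85, -5.28 and -5.28), C1QL1 (-4.27, -4.67, -2.73 and -3.10), RAX (-1.61, -2.08, -1.91 and -2.48) and EGLN3 (-1.14, -1.10, -1.18 and -1.13) fell.

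Lists of genes were then tested for pathways that move together, with 8, 16, 17 and 16 of the 37 lists called by camera in the order used above. Of these calls, 0 held with an estimated correlation. Values for lists below follow the same order. Fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes, called 13, 20, 20 and 15 lists. Without replicate number 2 camera called 21 lists for D425 hairpin 6, and without number 3 it called 4.

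Genes of the unfolded protein response, which encode chaperones and folding enzymes of the endoplasmic reticulum, were lower in every comparison. Of 21 tested members 11, 14, 13 and 13 fell and none rose (14, 15, 14 and 14 adjusted over the list alone), with medians of -0.37, -0.45, -0.45 and -0.45. Camera gave adjusted p = 3.4e-10, 2.4e-09, 3.9e-10 and 1.2e-09, and adjusted p = 0.375, 0.463, 0.488 and 0.591 with an estimated correlation. In D425, MANF changed by -0.80 ± 0.10 and -0.82 ± 0.10, HSPA5 by -0.83 ± 0.12 and -0.91 ± 0.12, PDIA3 by -0.46 ± 0.07 and -0.52 ± 0.07 and PDIA4 by -0.50 ± 0.08 and -0.63 ± 0.08. In D458, SDF2L1 changed by -1.26 ± 0.15 and -1.07 ± 0.15, XBP1 by -0.95 ± 0.12 and -1.05 ± 0.12, CALR by -0.55 ± 0.08 and -0.51 ± 0.08 and PDIA4 by -0.57 ± 0.08 and -0.63 ± 0.08. HSPA5 lies on the long arm of chromosome 9, which was lower as a whole in D425.

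The list of DNA replication and S phase was lower by camera with both hairpins in D458, where 20 of 46 members fell with both. With D425 hairpin 8 the list passed camera while few members passed (6 of 46, beside 1505 of all 14850 genes), and the difference between lines with hairpin 8 did not pass (camera adjusted p = 0.146). Of 46 members 3, 6, 23 and 26 fell (3, 3, 35 and 36 adjusted over the list alone; 4, 21, 39 and 43 with the block), with medians of -0.08, -0.26, -0.46 and -0.49. By camera the list had adjusted p = 0.0914, 7.0e-05, 2.3e-10 and 3.4e-12, and adjusted p = 0.809, 0.567, 0.488 and 0.591 with an estimated correlation. Fry did not call the list with D425 hairpin 8 (adjusted p = 0.14). In D458 the nucleotide enzyme DUT changed by -0.61 ± 0.10 and -0.54 ± 0.10, and the helicase subunits CDC45 (-0.74 ± 0.18 and -0.79 ± 0.18) and GINS1 (-0.67 ± 0.17 and -0.79 ± 0.17) fell, these 2 not without hairpin 7 replicate 1 (adjusted p = 0.0588 and 0.0655). In D425 hairpin 8 lowered the cyclin gene CCNE1 (-0.83 ± 0.13) and E2F1 (-0.74 ± 0.15), the latter on chromosome 20, which was also lower as a whole in D425.

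Genes that build ribosomes were lower with both D458 hairpins. With D425 hairpin 8 the list passed camera while few members passed (6 of 44, beside 1505 of all 14850 genes). Of 44 members of ribosome biogenesis 2, 6, 25 and 26 fell and 1, 0, 0 and 0 rose (0, 6, 28 and 30 lower adjusted over the list alone; 3, 10, 34 and 34 with the block), with medians of -0.04, -0.13, -0.31 and -0.32. Tested with camera, it had adjusted p = 0.189, 0.0061, 3.9e-10 and 9.3e-12, and adjusted p = 0.809, 0.598, 0.488 and 0.591 with an estimated correlation. In D458 UTP20 changed by -0.78 ± 0.15 and -0.87 ± 0.15, NOL6 by -0.46 ± 0.09 and -0.50 ± 0.09, and CIRH1A by -0.53 ± 0.11 and -0.56 ± 0.11. Fry did not call the list in D425 hairpin 8 (adjusted p = 0.165). Of 39 MYC targets 3, 7, 11 and 16 fell and 1, 1, 0 and 0 rose (2, 7, 12 and 17 adjusted over the list alone; 5, 13, 20 and 20 with the block). The camera test returned adjusted p = 0.264, 0.0020, 6.1e-05 and 9.5e-06, and adjusted p = 0.809, 0.567, 0.523 and 0.591 with an estimated correlation. PES1 changed by -0.45 ± 0.10 and -0.48 ± 0.10 in D458, and BOP1 (-0.49 ± 0.10) and NME2 (-0.45 ± 0.09) fell with D425 hairpin 8. For D425 hairpin 6 the mean of this list was 0.03 while its median (-0.04) and test were negative, and fry did not call it with D425 hairpin 8 (adjusted p = 0.11).

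The DNA repair list was lower by camera with both hairpins in D458, where 12 of 39 members fell and 1 rose with both. With D425 hairpin 8 the list passed camera while few members passed (4 of 39, beside 1505 of all 14850 genes), and the difference between lines with hairpin 8 did not pass (camera adjusted p = 0.0744). Of 39 members 1, 4, 13 and 17 fell and 1 rose in each comparison (1, 2, 22 and 22 lower adjusted over the list alone; 6, 10, 26 and 30 with the block). Camera gave adjusted p = 0.0914, 0.0350, 2.4e-07 and 6.7e-08, and adjusted p = 0.770, 0.598, 0.488 and 0.591 with an estimated correlation. The checkpoint kinase gene CHEK2 changed by -1.11 ± 0.17 and -1.22 ± 0.18 in D458, RBBP8 by -0.60 ± 0.10 and -0.48 ± 0.10, and BRCA1 by -0.75 ± 0.15 with hairpin 8. The end-joining ligase LIG4 went the other way and rose by 0.99 ± 0.12 and 1.13 ± 0.12. Fry did not call the list with D425 hairpin 8 (adjusted p = 0.20).

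Mitotic genes had medians of -0.21, -0.41, -0.31 and -0.32, but few of the 47 members passed: 1, 7, 2 and 3 fell (0, 4, 0 and 0 adjusted over the list alone; 16, 34, 37 and 34 with the block). By camera the list had adjusted p = 0.0054, 7.8e-06, 7.4e-05 and 3.8e-05, adjusted p = 0.753, 0.567, 0.638 and 0.667 with an estimated correlation, and fry called none of the 4 (adjusted p = 0.40, 0.14, 0.18 and 0.19). UBE2C (-0.85 ± 0.20) and AURKA (-0.90 ± 0.21) fell with D425 hairpin 8, and 5 of the 7 genes lower there lie on chromosome 20.

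Targets of p53 were higher in all 4 comparisons by camera, and the difference between lines with hairpin 8 did not pass (camera adjusted p = 0.509). Of 29 members 3, 6, 9 and 10 rose and none fell (1, 5, 12 and 13 adjusted over the list alone; 14, 14, 27 and 24 with the block). Tested with camera, it had adjusted p = 0.0412, 0.0185, 1.8e-06 and 3.0e-05, and adjusted p = 0.724, 0.598, 0.488 and 0.591 with an estimated correlation. In D458 the stress gene GADD45A rose by 0.94 ± 0.18 and 0.77 ± 0.18 and CYFIP2 by 1.26 ± 0.25 and 1.27 ± 0.25. FDXR rose by 1.04 ± 0.23 and 0.93 ± 0.23, the latter not without hairpin 8 replicate 1. Fry called this list only with D458 hairpin 7 (adjusted p = 0.032). Of 27 lysosome and autophagy genes 4, 6, 10 and 11 rose (6, 7, 10 and 14 adjusted over the list alone; 9, 10, 15 and 18 with the block), and 1 fell in each comparison. The camera test returned adjusted p = 0.0914, 0.0805, 0.0022 and 2.9e-04, and adjusted p = 0.717, 0.598, 0.488 and 0.591 with an estimated correlation. TFEB, the regulator of lysosome genes, rose in D458 by 2.52 ± 0.55 and 2.48 ± 0.55 and CTSB by 0.58 ± 0.13 and 0.65 ± 0.13, and in D425 CTSD rose by 0.73 ± 0.13 and 0.77 ± 0.13.

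Cholesterol synthesis and glycolysis were counted next. Of 25 cholesterol genes 4, 6, 17 and 7 fell and 0, 0, 1 and 1 rose (4, 6, 18 and 10 lower adjusted over the list alone; 4, 8, 18 and 12 with the block). Camera gave adjusted p = 0.0745, 0.128, 2.0e-06 and 0.0034, adjusted p = 0.697, 0.599, 0.488 and 0.591 with an estimated correlation, and fry did not call D458 hairpin 8 (adjusted p = 0.0612). FDFT1 (-0.54 ± 0.11) and SQLE (-0.64 ± 0.14) fell with D458 hairpin 7. Of 21 glycolysis genes 4, 6, 8 and 6 fell and 1, 1, 0 and 0 rose (5, 8, 8 and 8 adjusted over the list alone; 10, 12, 12 and 11 with the block). By camera the list had adjusted p = 0.0926, 0.0225, 0.0030 and 0.0125, the first of which was 0.00349 with the block, and adjusted p = 0.573, 0.466, 0.488 and 0.591 with an estimated correlation. ALDOA changed by -0.36 ± 0.07 and -0.40 ± 0.07 in D458 and by -0.31 ± 0.07 with D425 hairpin 8, and GAPDH rose with D425 hairpin 6 (0.42 ± 0.07).

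Cytosolic ribosomal proteins were lower with D425 hairpin 8 and higher with D458 hairpin 7 by camera, and did not pass in the other 2 comparisons. Of 51 members 5 and 13 fell in D425, and 6 and 4 rose in D458 (5 and 14 lower, 3 and 2 higher adjusted over the list alone). With the block 10 and 25 fell in D425, and 18 and 12 rose in D458. Tested with camera, it had adjusted p = 0.0914, 5.1e-06, 0.0081 and 0.0784, and adjusted p = 0.809, 0.554, 0.720 and 0.851 with an estimated correlation. Fry called it only with D425 hairpin 8 (adjusted p = 0.0424). With D425 hairpin 8, RPL7A changed by -0.85 ± 0.11, RPL35 by -0.66 ± 0.08 and RPL12 by -0.57 ± 0.10, all on the long arm of chromosome 9. Of the 13 members lower with this hairpin, only these 3 lie on that arm or on chromosome 20. In D458 RPL12 rose by 0.45 ± 0.10 and 0.47 ± 0.10, and RPL37 by 0.36 ± 0.07 with each hairpin.

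Photoreceptor genes, an expression trait of Group 3 tumours, were higher by camera with both D425 hairpins and with D458 hairpin 8, and did not pass with D458 hairpin 7. Of 44 members 9, 16, 11 and 13 rose and 3, 4, 4 and 2 fell (12, 16, 11 and 13 higher adjusted over the list alone; 12, 20, 16 and 19 higher and 8, 8, 7 and 3 lower with the block), with medians of 0.24, 0.61, 0.13 and 0.31. Genes under 1 CPM were also higher as a whole (medians 0.28, 0.43, 0.49 and 0.48), and 4 of the 44 members lay at that level. Random genes of like level, drawn after the list was seen, had medians of 0.02, 0.02, 0.03 and 0.03, and the list gave permutation p = 0.000999, 0.000999, 0.0709 and 0.00200 (1000 draws). Genes were drawn singly, so this p allows neither for members that vary together nor for spread between libraries. Levels here were averages over all 18 libraries of both lines. The camera test returned adjusted p = 0.0461, 0.0030, 0.134 and 0.0022, the hairpin 7 value being 0.0219 with the replicate block within line, and adjusted p = 0.444, 0.463, 0.523 and 0.591 with an estimated correlation. Fry called all 4. PDE6B rose by 2.43 ± 0.42, 2.66 ± 0.41, 2.31 ± 0.36 and 2.28 ± 0.36. EYS rose 2.12-fold and 2.46-fold in D425, as did RP1 (1.58 ± 0.26 and 1.61 ± 0.26) and IMPG1 (2.31 ± 0.39 and 2.66 ± 0.39). In D458 CRX rose by 1.12 ± 0.19 and 1.15 ± 0.19 and ABCA4 by 1.45 ± 0.30 and 1.70 ± 0.30.

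Mesenchymal and matrix genes were higher with both D425 hairpins and with D458 hairpin 7 by camera. Of 30 members 9, 11, 6 and 8 rose and 0, 1, 1 and 1 fell (10, 14, 6 and 8 higher adjusted over the list alone; 16, 17, 10 and 8 with the block). Camera gave adjusted p = 5.8e-05, 0.0018, 0.0130 and 0.108, the last of which was 0.0379 with the block, and adjusted p = 0.375, 0.463, 0.488 and 0.655 with an estimated correlation. The collagen gene COL1A1 rose by 3.05 ± 0.40 and 2.84 ± 0.39 in D425 and by 2.53 ± 0.46 with D458 hairpin 7, and MMP2 rose by 1.54 ± 0.26 and 1.85 ± 0.26 in D425. COL1A1 is also a fibroblast marker, and in D458 the fibroblast markers DCN (3.57 ± 0.56 and 3.43 ± 0.56) and PDGFRB (2.06 ± 0.35 and 2.09 ± 0.35) rose too. The adhesion receptor CD44 rose in D425 (3.35 ± 0.48 and 2.87 ± 0.49) and fell in D458 (-1.55 ± 0.34 and -1.77 ± 0.34). Of 30 immediate early genes 7, 6, 10 and 4 rose and 1, 1, 0 and 1 fell (8, 7, 17 and 4 adjusted over the list alone; 17, 14, 19 and 13 with the block). By camera the list had adjusted p = 0.0029, 0.0185, 5.4e-04 and 0.0459, adjusted p = 0.573, 0.567, 0.488 and 0.667 with an estimated correlation, and fry called only D458 hairpin 7 (adjusted p = 0.032). JUN rose by 1.47 ± 0.29 and 1.38 ± 0.29 in D425.

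**Figure D3:**
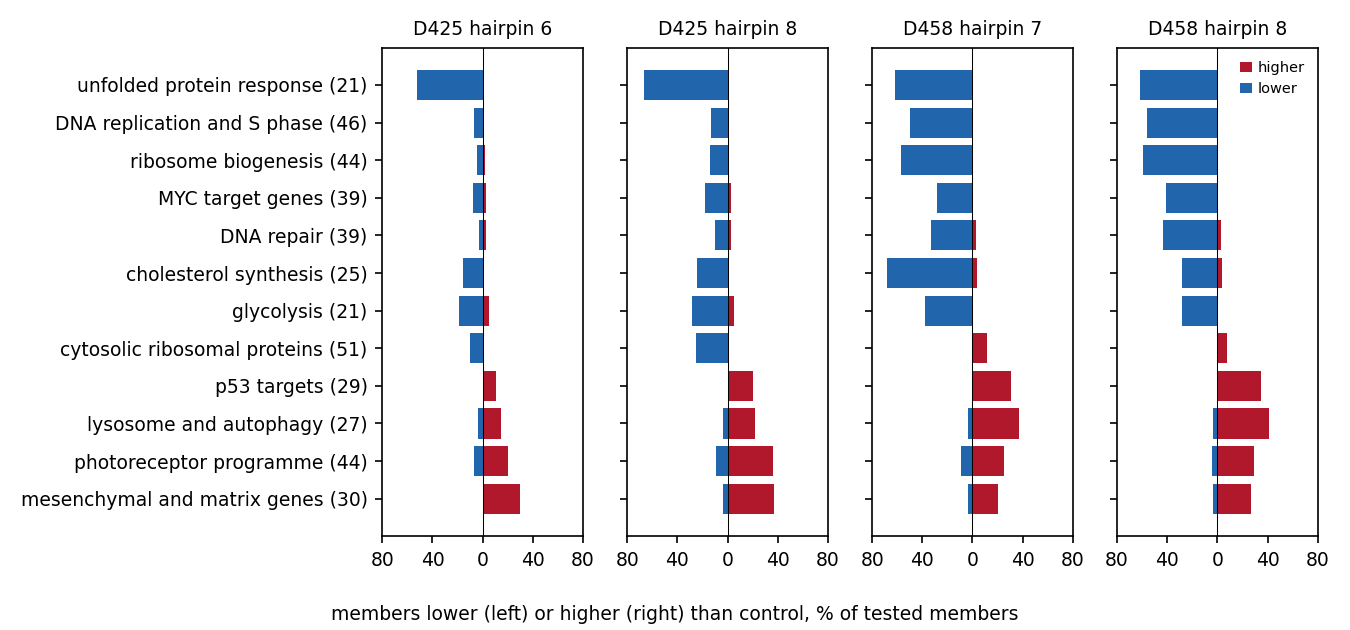
Percentage of the tested members of 12 gene lists that passed as lower (left) or higher (right) in each of the 4 hairpin comparisons. Members of the unfolded protein response were lower in all 4 comparisons.

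Hairpins of the same line were compared directly, to ask whether they differ beyond EYA2. In D425, hairpin 8 against hairpin 6 gave 0 genes with edgeR (519 at unadjusted p under 0.05, smallest adjusted p = 0.865) and 6 with DESeq2 (n = 3 per group). In D458, hairpin 8 against hairpin 7 gave 0 genes with edgeR (274 at unadjusted p under 0.05, smallest adjusted p = 0.951), 4 with DESeq2, 1 with the block and 2 in the 9 D458 libraries alone. EYA2 was the gene called with the block (-1.25 ± 0.15, adjusted p = 0.0110), and DESeq2 called it too (-1.25 ± 0.27, adjusted p = 0.0144). The D425 count was 16 without hairpin 8 replicate 2 and 1 without replicate number 2. Genes at unadjusted p under 0.05 in edgeR were 3.49% of those tested in D425 and 1.85% in D458. The block raised their number to 1495 in D425 and 738 in D458, so the counts of 0 do not show that the hairpins of a line act alike.

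The difference between lines in the hairpin 8 effect was tested as an interaction, D458 minus D425. It was called for 1758 genes, 919 with a more positive and 839 with a more negative change in D458, with n = 3 per group. WNK2 fell more in D458, with a difference of -2.77 ± 0.24 (adjusted p = 7.0e-06; -2.92 in D458, -0.15 in D425), and OR51B5 rose in D425 and fell in D458, -4.52 ± 0.46 (adjusted p = 3.1e-05). CRISPLD1 (5.81 ± 1.00, adjusted p = 0.0020), ZNF536 (4.44 ± 0.70, adjusted p = 0.0010) and PTPN3 (5.27 ± 1.08, adjusted p = 0.0058) rose in D458 alone. LPHN3 (-3.61 ± 0.65, adjusted p = 0.0026) and BRDT (-5.57 ± 0.88, adjusted p = 0.0010) fell in D458 alone. CD44 differed by -4.64 ± 0.60 (adjusted p = 2.3e-04), and the hedgehog genes GLI2 (4.02 ± 0.61, adjusted p = 9.0e-04) and SMO (1.07 ± 0.27, adjusted p = 0.017) rose in D458 only. SIX2 differed by 0.81 ± 0.16 (adjusted p = 0.0051), since it fell in D425 alone, while the EYA2 difference of -0.81 ± 0.38 did not pass (adjusted p = 0.177, 95% interval -1.63 to 0.02). OR51B5 and WNK2 kept the call in every leave-out, and the other genes named here lost it without replicate number 2 or 3 (highest adjusted p = 0.143 for SMO and 0.0755 for CD44).

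Ribosomal proteins differed between lines, 15 of 51 with a more positive change in D458 (18 adjusted over the list alone), median 0.23, camera adjusted p = 3.9e-08 and adjusted p = 0.963 with an estimated correlation, and fry did not call them (adjusted p = 0.158). RPL12 differed by 1.05 ± 0.15 and RPL7A by 1.01 ± 0.15. Both lie on the long arm of chromosome 9, which with hairpin 8 was lower as a whole in D425 (median -0.49) and not in D458 (0.01). Only 3 of the 51 members lie on that arm or on chromosome 20, so most of the list lies elsewhere. Ribosome biogenesis had 3 of 44 genes with a more negative change in D458 (3 adjusted over the list alone), median -0.18, camera adjusted p = 0.0175 and adjusted p = 0.963 with an estimated correlation, and fry did not call it (adjusted p = 0.346). UTP20 differed by -1.07 ± 0.20 and NOP10 by -0.43 ± 0.10. DESeq2 called 2421 genes in all and the replicate block 3029. The count was 1011 without D425 control 2, 946 without D425 control 3, 1048 without D425 hairpin 8 replicate 1, and 75 and 102 without replicate number 2 and 3.

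Control groups of the lines, which carried the non-targeting hairpin, were compared to describe cells in which EYA2 was not targeted. D458 and D425 differed in 9322 of 14850 genes, 4662 higher and 4660 lower in D458 (n = 3 per group). SOX11, a neural progenitor factor, stood at 111 CPM in D458 with no count in D425, at least 1053-fold higher, and THBS4 was at least 838-fold higher. COLEC12 was at 157 CPM in D425 and without counts in D458, at least 1162-fold lower, as were COL4A1 (at least 649-fold), ROR2 (at least 612-fold) and ALDH1A2 (at least 578-fold). EYA2 was higher in D458 by 1.33 ± 0.27 (adjusted p = 3.8e-04), while SIX2 was lower (-1.40 ± 0.12). EYA1 had 1860 counts in the D458 controls and 3 in those of D425. Neurofilament genes were higher in D458 (NEFL 8.34 ± 0.23, NEFM 9.73 ± 0.36). Of 32 neuronal genes 16 were higher and 5 lower (camera adjusted p = 0.0192, and adjusted p = 0.912 with an estimated correlation), and of 21 neural progenitor genes 12 were higher and 5 lower (camera adjusted p = 0.00487, and adjusted p = 0.364 with an estimated correlation).

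Changes were also laid along the chromosomes, in genes averaging at least 8 CPM, to see whether regions moved as blocks. In D425 the long arm of chromosome 9 (298 genes) was lower with both hairpins, with medians of -0.45 and -0.49, 91.9% and 90.3% of its genes below 0 and all 12 windows of 25 genes under -0.2. Its short arm (99 genes) was at 0.07 and 0.06. Chromosome 20, which carries EYA2, had medians of -0.28 and -0.31 over 267 genes, and chromosome 3 -0.18 and -0.19 over 555 genes (permutation p = 0.000999, the smallest possible with 1000 draws of random genes). Most chromosomes reached this p with each D425 hairpin, so it did not single these out. Among them were chromosome 17 (-0.10 and -0.12) and, with hairpin 6, chromosome 1 at 0.012 beside -0.014 over all genes. In D458 the long arm of chromosome 9 was at 0.01 with each hairpin and chromosome 20 at -0.08, while chromosome 18 (138 genes) was at -0.24, chromosome 16 (477 genes) at -0.18 and -0.20 and chromosome 13 (173 genes) at -0.17 and -0.15. Each D425 replicate carried the pattern, with medians on the long arm of chromosome 9 of -0.34, -0.47 and -0.53 for hairpin 6 and -0.40, -0.50 and -0.58 for hairpin 8 against the same-numbered control. Among genes at this level, 731 were lower with both D425 hairpins, and 290 of them (39.7%) lay on the long arm of chromosome 9 or on chromosome 20, which hold 5.78% of the genes at this level. EYA2 differed from the chromosome 20 median by -0.95 and -0.67 in D425. The hairpin 8 margin leaned on control replicate 1, without which the EYA2 change was -0.51. In replicate 3 of hairpin 8, EYA2 (-0.29) was not below chromosome 20 (-0.33) against the same-numbered control.

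**Figure D4:**
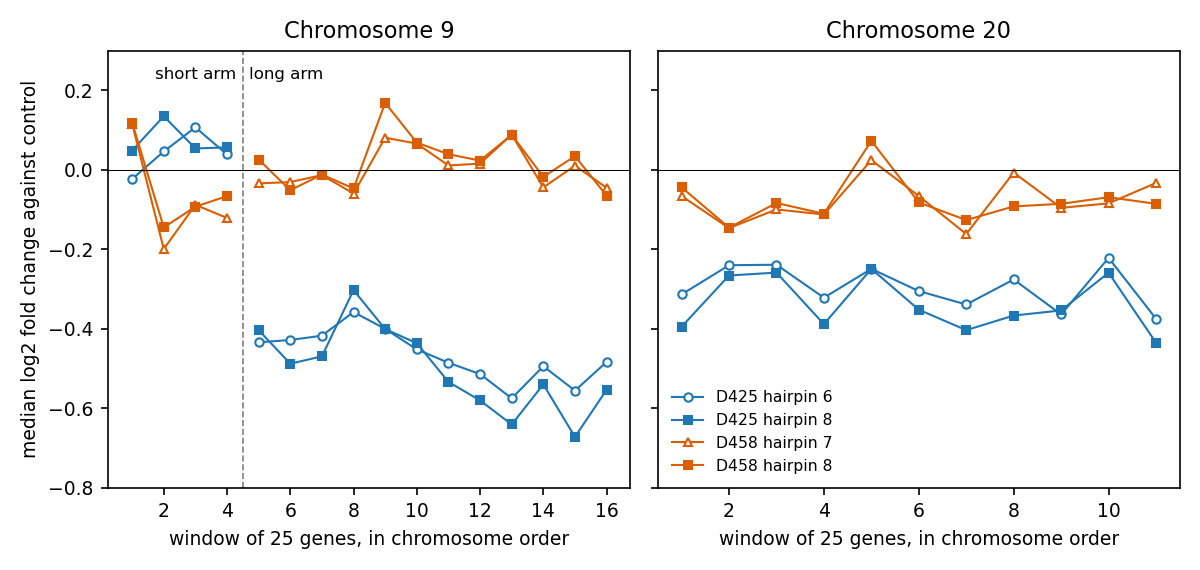
Median log2 fold change against control in windows of 25 genes in order along chromosomes 9 and 20, for the 4 hairpin comparisons; the dashed line separates short and long arm. The long arm of chromosome 9 and all of chromosome 20 were lower in D425.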

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

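The tests of the hairpin similarity, the EYA2 explanation of the chromosome pattern, the scaling test, the test of background reads, and the regrouping of libraries for single comparisons and for the difference between lines were chosen after seeing the results; the tests of gene copies, GC content and length and replicate 1, and the regrouping for genes shared by both hairpins, were written before their values were computed.

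In D425, genes on the long arm of chromosome 9 and on chromosome 20 were lower with both hairpins, and the arm boundary was set after the windows were seen. If cells in the hairpin groups carried fewer copies of these regions than control cells, genes of low, middle and high expression should all be lower. Among genes averaging at least 8 CPM, the weakest median over these levels, both regions and both hairpins was -0.277. The regions were picked because their genes were lower throughout, so a low median at each level was likely beforehand. Any other lowering of a whole region predicts the same, so this result does not tell whether copies were fewer. DNA was not measured here. A loss in hairpin cells and a gain in control cells predict the same, so the test does not tell which group changed. On the long arm of chromosome 9 the D425 controls were unequal, at 0.15, 0.36 and 0.42 (median log2 relative to the line mean). The D425 hairpin libraries ran from -0.26 to -0.10. After removal of a trend on GC content and transcript length the weakest median was -0.331, so that trend did not account for the pattern. Loss of EYA2 lowering the arm in both lines would need a lower median in D458 with hairpin 8, where it was 0.0112.

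The 2 hairpins of a line gave nearly the same changes, although EYA2 fell 3.27 times as far on the log2 scale with hairpin 8 as with hairpin 7 in D458. Counting noise of shared controls did not account for it, with covariances of 0.503 in D425 and 0.588 in D458 against simulated means of 0.0617 and 0.0795; the simulation left out what same-numbered libraries share, and in log2 ratios to same-numbered controls the covariances were 0.358 and 0.352, of which spread between replicate numbers gave 0.0459 and 0.0362, and 0.0647 and 0.0631 if replicates 2 and 3 count as 1 date (computed after seeing the result). A response in proportion to the log2 fall of EYA2 would give a slope above 2, and the slope was 0.975 with a jackknife standard error of 0.0146. That error is over 24 chromosome blocks of genes and does not measure spread between libraries. The bound of 2 rests on the ratio of 3.27, given without error, while the hairpin 7 change of EYA2 (-0.55 ± 0.26) did not pass. Against same-numbered controls EYA2 changed by -0.64, -0.38 and -0.63 with hairpin 7 and -2.02, -1.52 and -1.85 with hairpin 8. How firmly the slope speaks against a proportional response is therefore not known. A threshold or saturating response was not tested. In D425 the lower chromosome regions were part of the similarity. Of 731 genes averaging at least 8 CPM and lower with both hairpins, 290 (39.7%) lay on the long arm of chromosome 9 or on chromosome 20. That arm was at 0.01 with each hairpin in D458, so a fall of EYA2 that lowers it in both lines would not give this part. Over all genes, whether control cells differed from hairpin cells for another reason could not be told, since each line had 1 control construct.

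Genes of low abundance were higher with hairpins in both lines, with medians for genes under 1 CPM of 0.28, 0.43, 0.49 and 0.48. A scaling factor would shift all levels alike, and the smallest difference between the lowest and highest levels was 0.306. Without replicate number 1 the smallest median was 0.215, just over the bound of 0.2, and the condition on its standard error (0.037) was added after the value was seen, so this margin is thin. Whether background reads from DNA or unspliced RNA contribute could not be told: summed olfactory receptor counts were at least 1.21 times the control without OR51 and OR52 genes, but these were left out after the sum over all such genes was seen, which was 0.505 times the control with D458 hairpin 7.

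The hairpin 8 effect differed between lines for 1758 genes, and the cause was not tested. The named genes with more than 3 counts in every group were CILP (-6.28), CRISPLD1 (5.81), KRT17 (-2.86), LPHN3 (-3.61), NDUFA4L2 (2.23), OR51B5 (-4.52), PTPN3 (5.27), SAG (4.54), SIX2 (0.81), SLCO4A1 (-3.75), WNK2 (-2.77) and ZNF536 (4.44), as log2 differences D458 minus D425. By camera ribosomal proteins differed by a median of 0.23 and ribosome biogenesis by -0.18 (3 of 44 genes called), but neither passed with an estimated correlation (adjusted p = 0.963 for both) or with fry (adjusted p = 0.158 and 0.346). Only OR51B5 and WNK2 of the 12 kept the call without replicate number 2 and without number 3. SAG also lost it in 10 of 12 single leave-outs (highest adjusted p = 0.141), KRT17 in 7 of 12 (highest 0.201), CILP without D425 hairpin 8 replicate 1 (-5.40, adjusted p = 0.136) and NDUFA4L2 without D425 control 2 (adjusted p = 0.0502).

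Regrouping the 6 libraries of a single comparison allows 10 splits, too few for a share under 0.05. The true grouping ranked first (1 of 10 splits gave as many genes, the true one) for D425 hairpin 6 (2101 genes, highest other 0), D425 hairpin 8 (3221, highest other 1), D458 hairpin 7 (3357, highest other 0), D458 hairpin 8 (3442, highest other 0) and the control lines (9322, highest other 0). For the hairpins of a line against each other, where the count was 0, all 10 of 10 splits gave as many, the highest other being 4 in D425 and 396 in D458. The D458 split with 396 genes put hairpin 7 replicates 1 and 2 with hairpin 8 replicate 1. Among 50 splits, only the true one (1 of 50) gave as many genes shared by both hairpins, 1845 in D425 (highest other 2) and 2661 in D458 (highest other 363). Other splits whose control group came whole from 1 true group were not drawn. Splits that keep the controls together and shuffle only the hairpin libraries were thus left out, and these could have matched the true count. For the difference between lines 2 of 100 splits gave at least 1758 genes, the other with 1902, which kept the D425 groups and mixed those of D458, so this count also contains effects of a single line.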

How the results depend on the processing

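With the replicate number as a block the counts were 4134 (D425 hairpin 6), 5521 (D425 hairpin 8), 5937 (D458 hairpin 7) and 5888 (D458 hairpin 8), 3564 and 4867 genes were shared by both hairpins in D425 and D458, 3029 differed between lines, 1 differed between D458 hairpins, and EYA2 passed with hairpin 7 (-0.55, adjusted p = 0.00692); the block changed no other call among these counts and the EYA2 changes against control, while it changed calls of named genes (below) and of lists (given in the report), and the cause was not tested. In the 9 libraries of a line alone, EYA2 did not pass with D425 hairpin 8 (-0.98, adjusted p = 0.0759), passed with D458 hairpin 7 (-0.55, adjusted p = 0.00819), and 2 genes differed between D458 hairpins. DESeq2 called 6 genes between D425 hairpins and 4 between D458 hairpins. With an estimated correlation camera called 0 lists in each of the 4 hairpin comparisons (8, 16, 17 and 16 at the preset), and fry called 13 for D425 hairpin 6. Leaving out 1 library or replicate number, which also leaves fewer libraries, gave 116 to 3439 genes for D425 hairpin 6, 513 to 4146 for D425 hairpin 8, 663 to 2910 for D458 hairpin 7, 818 to 3311 for D458 hairpin 8, 111 to 2884 shared in D425, 531 to 2465 shared in D458, 75 to 2322 for the difference between lines, 0 to 16 between D425 hairpins and 4 to 21 lists for D425 hairpin 6. EYA2 ran from -1.53 to -0.76 with D425 hairpin 6, not passing without replicate number 2 (-1.26, adjusted p = 0.154) or 3 (-1.40, adjusted p = 0.0542), and from -1.28 to -0.51 with D425 hairpin 8, not passing without control 1 (-0.51, adjusted p = 0.0865), hairpin 8 replicate 2 (-0.89, adjusted p = 0.0571), hairpin 8 replicate 3 (-0.92, adjusted p = 0.0601) or replicate number 2 (-0.97, adjusted p = 0.168). Of 804 named gene values DESeq2 left 785 calls unchanged (11 gained, 8 lost), RLE factors 799 (1 gained, 4 lost) and no low-count filter 763 (41 lost); the block within a line left 515 of 528 (12 gained, 1 lost), the shared block 270 of 276 (6 gained) and the 9 libraries of a line changed calls among 515 (2 gained, 55 lost). Without replicate number 1, 2 and 3, 725 of 798, 410 of 802 and 407 of 804 were unchanged, and none reversed direction. Alternatives chosen after seeing the data left out chromosomes 3, 9 and 20 in D425 (1414 and 2397 genes, with 1230 D425 genes called with both hairpins) and 13, 16 and 18 in D458 (3025 and 3090, with 2381 D458 genes called with both hairpins). At 21260369 to 31552051 counts per library, genes of few counts, such as MYCN, were at the limit of what could be compared.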

Other observations

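The tests in this part were fixed before the data were examined, except those of CMTR1, of olfactory receptors, of chromosomes left out, of other hairpin against hairpin genes, of fibroblast marker levels and of shared list members with the block, which were chosen after seeing the result.

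CMTR1, an mRNA cap methyltransferase chosen after its values were seen, fell with hairpin 8 in both lines and did not pass with hairpins 6 and 7. It stood at 108 ± 6.59 CPM in D425 control, 117 ± 5.50 with hairpin 6 and 55.0 ± 30.1 with hairpin 8, and at 193 ± 19.5 CPM in D458 control, 182 ± 18.6 with hairpin 7 and 79.2 ± 13.6 with hairpin 8. The D425 hairpin 8 libraries were at 36.8, 89.7 and 38.4 CPM, the second close to its control (102.9). Its hairpin 8 changes were -0.98 ± 0.25 (adjusted p = 0.011) in D425 and -1.28 ± 0.25 (adjusted p = 0.0027) in D458. The D425 change was -1.53 ± 0.14 without hairpin 8 replicate 2 and did not pass without hairpin 8 replicate 1 (-0.76 ± 0.24, adjusted p = 0.0523). Against the other hairpin of the line, DESeq2 called CMTR1 in both lines (adjusted p = 0.0241 and 0.0044) and edgeR in neither (adjusted p = 1 and 0.951), nor in the mean of both lines (-1.15 ± 0.18, adjusted p = 0.113, 0 genes called and 710 at unadjusted p under 0.05). The other genes DESeq2 called between D425 hairpins were DIXDC1 (0.50), GPR176 (-0.58), MMD (0.35), NBEA (0.45) and RAD51C (-0.48), and between D458 hairpins EYA2, HMHA1 (-0.57) and RAB4A (0.39).

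Of 7 tested fibroblast and endothelial markers 3, 3, 4 and 4 rose with hairpins (3, 4, 4 and 4 adjusted over the list alone). Camera returned adjusted p = 0.0461, 0.0061, 9.2e-04 and 0.0022, the first of which was 0.0627 with the replicate block within line, and adjusted p = 0.375, 0.463, 0.488 and 0.591 with an estimated correlation. In D425 the markers were COL1A1, LUM and the endothelial receptor KDR (1.06 ± 0.31 and 1.33 ± 0.31). With hairpin 6, KDR did not pass when any single library but control 2 was left out (highest adjusted p = 0.177), and with hairpin 8 it did not pass without control 3 (adjusted p = 0.0527). The LUM change with hairpin 6 did not pass when any single library was left out (highest adjusted p = 0.163), nor did that with hairpin 8 without control 3 or hairpin 8 replicate 3 (highest adjusted p = 0.0592). DCN rose in D458 by 3.57 ± 0.56 and 3.43 ± 0.56, and LUM from 1.43 CPM to 8.42 and 10.5, while DCN in D425 did not pass. PDGFRB rose in D458 by 2.06 ± 0.35 and 2.09 ± 0.35, from 4.19 CPM to 17.5 and 17.8.

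Summed over all 378 olfactory receptor genes, levels were 4.24 and 3.72 times the control in D425 but 0.505 and 0.600 times in D458, where the control stood at 64.1 CPM. After these sums had been seen, genes with names starting with OR51 and OR52, among them the changed gene OR51B5, were left out. Over the remaining 332 genes levels were 2.89 ± 0.53 CPM in D425 control, 4.39 ± 0.76 with hairpin 6 and 3.50 ± 0.64 with hairpin 8. In D458 they were 0.821 ± 0.174, 1.76 ± 0.30 with hairpin 7 and 1.36 ± 0.32 with hairpin 8. The ratios to control were 1.52, 1.21, 2.15 and 1.66.

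Leaving out chromosomes 3, 9 and 20, the share of changed D425 genes that were higher went from 51.7% to 63.9% with hairpin 6 and from 53.3% to 62.7% with hairpin 8. These chromosomes were picked because their genes were lower, so a rise in the share follows from that choice.

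Other lists are given as members higher and lower with both hairpins of a line. In D425 neuronal genes had 4 and 4, neural progenitor genes 6 and 0, hypoxia genes 2 and 3, ATF4 targets 2 and 4, Notch targets 3 and 1, WNT targets 2 and 1, TGF-beta targets 2 and 0, hedgehog targets 1 and 0, oxidative phosphorylation 1 and 1, NF-kB 1 and 0 and the MYC family 0 and 1. In D458 the same lists had 2 and 2, 2 and 0, 1 and 2, 4 and 4, 1 and 0, 2 and 1, 3 and 0, 2 and 0, 4 and 1, 1 and 1, and 2 and 1. Apoptosis regulators had 0 and 0 in D425 and 4 and 1 in D458, interferon-stimulated genes 0 and 0, and 2 and 0, and histones 0 and 0, and 1 and 0. With D425 hairpin 8 alone 6 of 17 interferon-stimulated genes rose. With the block, counts in D425 were 15 and 5 for neuronal genes, 8 and 1 for neural progenitor genes, 4 and 5 for hypoxia genes, 2 and 6 for ATF4 targets, 4 and 2 for Notch targets, 2 and 2 for WNT targets, 5 and 1 for TGF-beta targets, 1 and 2 for hedgehog targets, 2 and 2 for oxidative phosphorylation, 5 and 0 for NF-kB and 1 and 2 for the MYC family. In D458 the block gave 8 and 4, 2 and 2, 3 and 5, 8 and 7, 1 and 1, 2 and 3, 5 and 0, 3 and 0, 6 and 3, 4 and 1, and 2 and 2. For apoptosis regulators it gave 2 and 1 in D425 and 8 and 3 in D458, for interferon-stimulated genes 5 and 0 in each line, and for histones 0 and 2 in D425 and 8 and 0 in D458. SOX4 rose in D425 by 0.68 ± 0.11 and 0.78 ± 0.11, PROM1 in D458 by 0.86 ± 0.09 and 0.98 ± 0.09, and the chemokine gene CCL2 in D425 by 2.58 ± 0.35 and 2.96 ± 0.35. GLI2 rose 16.1-fold and 12.2-fold in D458, and BOK by 1.40 ± 0.19 and 1.39 ± 0.19. GRIN1 fell in D425 (-1.85 ± 0.38 and -2.17 ± 0.39).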
